A study of Solanum tuberosum with 22 samples.

How the data were processed

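RNA of 10 in vitro microtuber samples and 12 in vivo stolon and tuber samples was hybridised with a pooled reference on 2-colour arrays, per the labels. Each system had its own reference, a pool of the RNA of its stages. Stolon RNA was amplified to cRNA before labelling and the other samples were labelled as total RNA, per the labels. The growth protocol in the labels describes the culture medium also for the in vivo samples. The submitters' processing notes name limma with no version, and background correction, normalization and spot filtering are not given in the sources used here.

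The deposited values are log2 ratios. They equal the log2 of a ratio with 2 decimals, within 0.001, for 100% of values, with a lowest ratio of 0.01. The median of every array lay between -0.058 and 0.029, so values were used as deposited by the rule fixed in advance, with median-centred values as an alternative. Whether each array was centred by the authors, and the order of sample and reference in the ratio, are not stated. Of 32448 spots, 9740 had no value on any array and 6848 had a value on every array. Duplicate spots of a clone correlated between 0.79 and 0.97 within an array.

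The direction of the ratios was examined by correlation. In vitro replicates correlated between 0.61 and 0.79 and in vivo replicates, labelled with opposite dyes, between -0.63 and -0.36. The plan was to turn the arrays whose sample was Cy3, which are the in vivo arrays of replicate 1. Replicate 2 was turned instead, a choice made after the data were examined. In vitro, 2 and 4 values lay above the bound of an equal pool of 5 (log2 of 2.32) and 282 and 286 lay as far below it. In vivo, 413 values of replicate 1 lay above the bound of an equal pool of 6 (2.58) and 2070 below, and in replicate 2, as deposited, 1781 lay above and 46 below. Patatin was lowest in stolons with this choice. The labelled dyes would then give different dye orders in the 2 systems, so the in vivo direction remains unsettled. Turning it swaps higher and lower in each in vivo comparison and changes the comparison between systems, for which both values are given. After turning, in vivo replicates correlated between 0.36 and 0.63. Within a dye orientation the lowest correlation between arrays was -0.63 in vitro (2 and 20 days) and -0.56 in vivo (stolon and 26-35 mm), between stages that could oppose each other.

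A spot was tested if it had a value on at least 80% of the arrays of a fit and at least 1 in each group. Log2 ratios were fitted by least squares with moderated statistics from limma 3.58.1 in R 4.3.3, with exact handling of missing values. On spots with every value p-values differed from those of limma by at most 5e-16. The in vitro and in vivo arrays were fitted apart, and the difference between them over all 22 arrays. Calls have a Benjamini-Hochberg adjusted p under 0.05. On simulated data for in vitro late against early times, with 50 of 19600 spots changed at each size, 96% were recovered at a log2 change of 1 and 22% at 0.5. For large against small tubers, with 10415 spots, 6% were recovered at 1, 54% at 2 and 92% at 4. For tubers against stolon 34% were recovered at 2 and 72% at 4. Each simulation changed 200 spots in all, whereas the data called 48.5% of spots for late against early times and 22.3% for tubers against stolon. The Benjamini-Hochberg cut-off loosens with more changes, so recovery in those 2 comparisons may differ from the simulated one and be higher.

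The in vivo replicate number marks the sets of plants grown in sequence, per the labels, and also the dye of the sample, so it pairs the samples. Deviations from the stage means correlated over 0.1 in 10 of 15 pairs of in vivo stages, with a median of 0.86 and a lowest value of -0.47. Pairs of tuber classes lay between 0.85 and 0.93, and pairs of the stolon with a tuber class between -0.47 and -0.37. A block shared by stolons and tubers therefore does not describe the stolons, and fits that use it carry this limit. Fits with the replicate as a block are given beside a result where they change it.

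Spots were named through the platform annotation and gene identifiers matched to the SolTub_3.0 gene table for 430 of 430 genes. A readable name was held by 197 genes with 726 spots, and spots with several genes were not named. Named genes were chosen by a rule fixed before the data were examined. For each gene the spot with the smallest p was kept among those past the threshold and alike in sign in both replicates. Of these, up to 10 each way with the largest change were named, and 5 each way for the difference between systems. The rule also took up to 4 spots of each fixed list. Where fewer passed, those with the smallest p are given as not past the threshold. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, on members with a value on every array of the system. The lists matched to no spot were not tested. Lists by symbol and gene means were added after the data were examined. A gene mean averaged, on each array, the spots of the gene that had a value there. The spots behind a mean over all spots could therefore differ between arrays, as for dnaJ with 97 of 160 possible in vitro values. Alternatives were the replicate block, median centring, quantile normalization, stricter and looser filters, a robust spread, array weights, a 2-fold minimum, only the groups compared, fits without stolons, the other in vivo direction and leaving out each array. Averages over the spots of a clone, and the block together with the removal of stolons, were added after the data were examined.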

Results

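Transcript levels were measured during tuber formation of potato (Solanum tuberosum) on spotted arrays carrying 32448 spots, each array comparing a sample with a pool of RNA. Microtubers, small tubers formed on plantlets in tissue culture, were sampled 2, 5, 10, 20 and 30 days after tuber induction. Tubers of growth chamber plants were sampled as stolons, the underground shoots from which tubers form, and as tubers of 1-5, 6-10, 11-15, 16-25 and 26-35 mm. Each of the 5 culture times and 6 size classes had 2 replicates, which gave 10 in vitro and 12 in vivo arrays. In vitro replicates came from separate microtuber populations and in vivo replicates from separate sets of plants grown in sequence. The in vitro arrays had values for 52.0% to 65.7% of spots and the in vivo arrays for 33.1% to 48.9%. The small number of arrays limits the precision of every value given here. Of the spots, 1630 were listed with 1 gene, 180 with several and 30638 with none, so the named genes cover a small part of the arrays. Changes are log2 values with the standard error of the limma fit, and adjusted p-values are Benjamini-Hochberg values over all spots tested.

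The first comparison asked which transcripts changed as microtubers aged. Late times were 20 and 30 days and early times 2 and 5 days. A dnaJ chaperone transcript was 2.58 ± 0.14 higher on the log2 scale at the late times (adjusted p = 1.27e-06). This was the largest rise among named genes with tested spots, and all 9 dnaJ spots tested rose. The storage protein patatin and the protease inhibitors KTI-C and API had too few in vitro values to be tested. The phospholipase C transcript plc3 rose by 1.87 ± 0.11, the late embryogenesis transcript Lea by 1.58 ± 0.20 and the lipoxygenase POTLX-3 by 1.45 ± 0.10. METK1, an S-adenosylmethionine synthase, was higher on all 17 of its tested spots, each past the threshold, with changes from 0.66 to 1.87. The alpha-amylase AMYA1, which acts in starch breakdown, rose by 1.17 ± 0.14. Named spots of pp34, VPE2, StMYB1R-1 and STUGE45 rose by more than 1, while as means over all spots VPE2 rose by 0.74 and STUGE45 by 0.92. The proteinase inhibitor PIN-II changed by -2.06 ± 0.29 on the named spot (adjusted p = 2.89e-04) and by -1.66 ± 0.23 as the mean of its 8 spots. SGA, listed also as Sgt3, a name of glycoalkaloid glycosyltransferases, changed by -2.02 ± 0.10, the alcohol dehydrogenase ADH1 by -1.91 ± 0.15, the protein kinase StMPK4 by -1.63 ± 0.12 and OEE2, a protein of photosystem II, by -1.61 ± 0.13. Named spots of EI1, PEST2, CS-B, TK and Cyp fell by 1.49 to 1.72. As means over all spots the changes were smaller for CS-B (-0.97 over 10 spots), Cyp (-0.88 over 12), StMPK4 (-1.27 over 4) and OEE2 (-1.23 over 6). The spots with no gene name that changed most had values at the lowest ratio of 0.01, so their changes are not ranked.

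**Figure D1:**
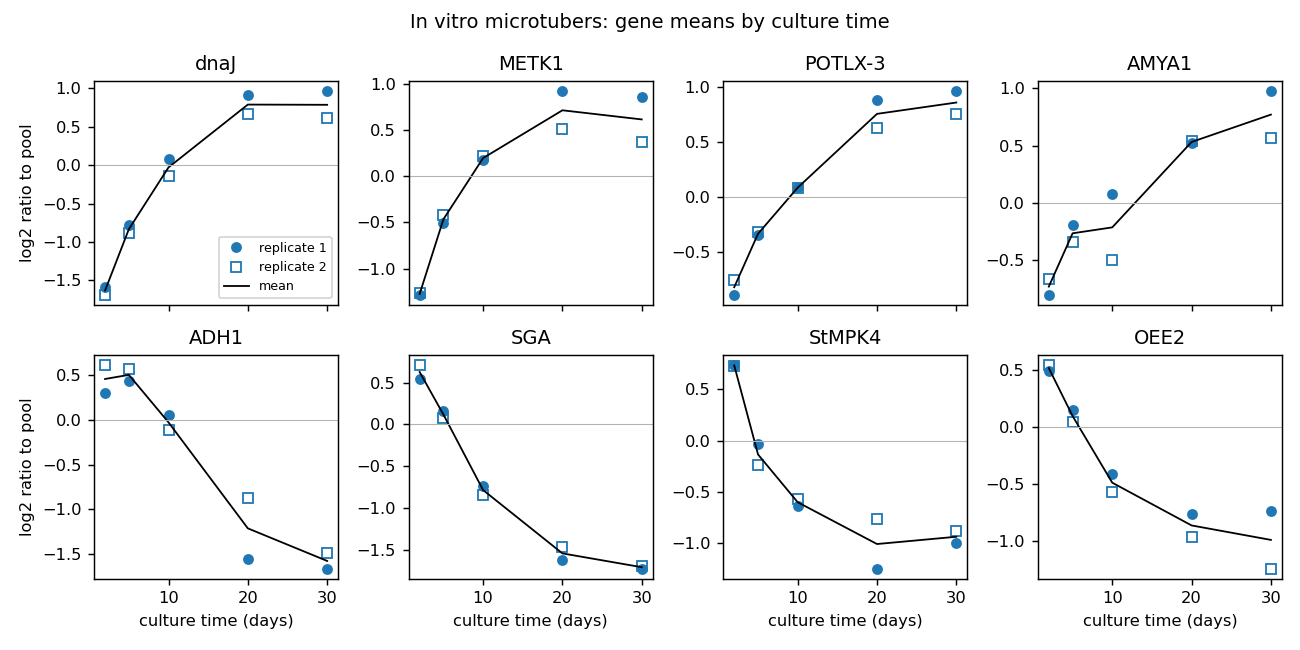
Mean log2 ratio to the reference pool (vertical axes, which differ in range) against culture time in days (horizontal axes) for 8 genes. Each mean is over the spots of the gene with a value on that array. A symbol is drawn for each of the 2 replicates and a line through their means. The mean of dnaJ went from -1.63 at 2 days to 0.78 at 30 days, and that of SGA from 0.63 to -1.71.

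Over all spots, 4749 of 19600 rose and 4766 fell between the early and late times, of which 879 and 1125 changed at least 2-fold. Compared with 2 days, 1076 spots differed at 5 days, 5051 at 10 days, 8206 at 20 days and 7956 at 30 days. The test of any difference among the 5 times called 7212 spots. Of the 25 gene lists fixed before the data were examined, 18 matched no spot and 4 had 3 or more spots, since the annotation holds mostly symbols. The heat shock and chaperone list, which here is the dnaJ gene alone, had 9 of 9 tested spots higher, also 9 when adjusted over the list alone. Its list test used the 4 spots with a value on every array (camera adjusted p = 0.00118, and adjusted p = 0.359 with an estimated correlation). In the cytoskeleton list, which is the actin gene AC97 alone, 1 of 6 spots rose, and 0 when adjusted over the list alone. In the auxin list, 0 of 4 spots of IAA2 and IAA3 passed, also 0 when adjusted over the list alone. In the gibberellin list, 1 of 2 spots of sn1 fell, and 2 when adjusted over the list alone. The invertase InvCD111 and a chitinase, each the only gene of its list, had 0 of 2 spots past the threshold, also 0 when adjusted over the list alone.

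Further lists were compiled by symbol only after the values had been seen, so their tests, run on means over the spots of a gene, are not independent evidence. Among 11 genes of mitochondrial respiration, 9 fell with culture time and 1, the alternative oxidase AOX, rose (camera adjusted p = 0.0401, and adjusted p = 0.482 with an estimated correlation). Fumarase changed by -1.03 ± 0.08, mitochondrial malate dehydrogenase by -1.16 ± 0.12 and the uncoupling protein UCP by -0.97 ± 0.07. All 3 genes of sterol and glycoalkaloid synthesis fell, with too few complete members for a list test. Over all genes, 152 of 408 means fell and 125 rose past the threshold, so falls were common and the counts of these lists are read against that share. Of 9 MAP and calcium-dependent protein kinases, 6 fell and 1 rose (camera adjusted p = 0.229). Of 4 genes of the cell cycle and cytoskeleton, 3 fell (camera adjusted p = 0.553), among them the D-type cyclins CYCD3.2 and CYCD3.3. Of 8 starch genes tested, 2 rose and 3 fell (camera adjusted p = 0.955).

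The in vivo comparisons need a statement on direction first. Replicates of the same in vivo stage had opposite dyes and correlated between -0.63 and -0.36 across spots as deposited, so the sign of replicate 2 was turned. Which replicate to turn is not settled by the labelled dyes, and the plan made before the data were examined would have turned replicate 1. The direction used here is only likely. It rests on the tails of the values, since a member of an equal pool of 6 can fall far below the pool but not over 6-fold above it, and on the tuber storage protein patatin, which is background knowledge. With the other choice every in vivo rise reads as a fall of the same size and adjusted p. Because storage proteins helped to set the direction, their higher level in tubers is not an independent finding.

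The next comparison asked what sets tubers apart from stolons. The Kunitz inhibitor KTI-C was 8.09 ± 0.72 higher on the log2 scale in tubers (adjusted p = 8.55e-04), patatin 7.17 ± 0.35 (adjusted p = 5.12e-04) and the protease inhibitor API 5.58 ± 1.03. The stolon value of replicate 1 of both KTI-C and patatin was at the lowest ratio, 0.01, so the sizes of these changes are limited by it. CYP74D2, the divinyl ether synthase, was 3.63 ± 0.61 higher. GA2OX1, an enzyme that inactivates gibberellins, was 3.26 ± 0.49 higher and BEL5, a homeodomain factor known from tuber induction, 3.24 ± 0.53. Starch-related transcripts dpeP, glgP and GBSS-II were higher by 2.89 ± 0.52, 2.62 ± 0.44 (1.71 ± 0.30 as the mean of 6 spots) and 2.30 ± 0.36. PIN-II was 3.11 ± 0.73 higher on the named spot, but 0.94 ± 0.38 as the mean of 8 spots (adjusted p = 0.129, and 0.043 with the block). ADH1 was 3.71 ± 0.97 higher, with 1.28 in replicate 1 and 6.14 in replicate 2. Lower in tubers were FLS (-5.54 ± 1.32 on the named spot and -2.30 ± 0.48 as the mean of 8 spots), the aquaporin-like XIP1-1-BETA (-3.54 ± 0.44), the catalase CAT1 (-3.07 ± 0.93) and the photosystem II transcripts PSBR (-2.88 ± 0.76) and MSP-II (-2.16 ± 0.55). METK1 was lower on the named spot (-2.49 ± 0.52), but its 16 tested spots ranged from -3.39 to 1.61 and 3 passed the threshold. PSBR passed on 1 of 8 spots, and the means over all spots of CAT1 (-1.86 ± 0.67, adjusted p = 0.0933), PSBR (adjusted p = 0.131) and METK1 (adjusted p = 0.336) did not pass. With the replicate block these means passed, with adjusted p = 0.0149, 0.012 and 0.0424, and over all gene means the calls went from 41 higher and 22 lower to 64 and 89. That block is shared by stolons and tubers, whose replicate deviations correlated between -0.47 and -0.37. Blocked values of this comparison are therefore no firm support.

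**Figure D2:**
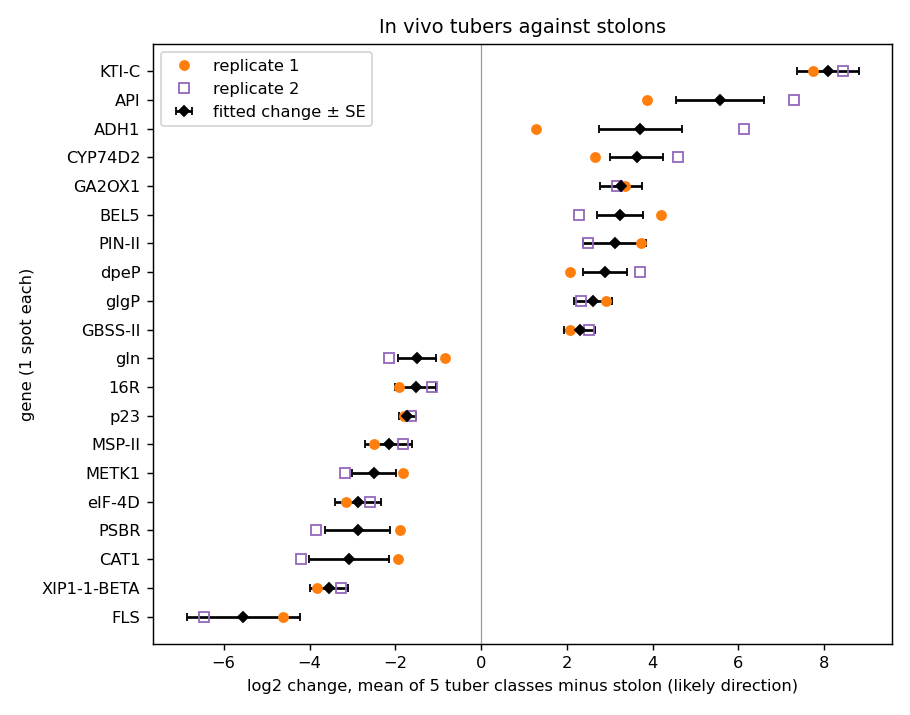
Log2 change between the mean of the 5 tuber classes and the stolon (horizontal axis, in the likely direction) for 20 named genes, 1 spot each (vertical axis). Diamonds with bars give the fitted change and its standard error, and the other symbols the change in each of the 2 replicates, as for ADH1 with 1.28 and 6.14.

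In total 1485 of 10415 spots were higher and 839 lower in tubers, and with the replicate as a block 2266 and 1860. The planned fit takes the tuber classes as independent, although their replicate deviations correlated at 0.85 to 0.93. Its standard errors in this comparison may be too small and its calls too many. The blocked calls may also be too many, since the stolons do not share the replicate deviations of the tubers. With the other direction 839 would be higher and 1485 lower. The count was 1180 without stolon replicate 1 and 366 without stolon replicate 2. Stolon RNA was amplified before labelling and tuber RNA was not, so tissue and amplification cannot be told apart in this comparison. Against stolon, 766 spots differed in 1-5 mm tubers, 916 in 6-10 mm, 1419 in 11-15 mm, 1130 in 16-25 mm and 1364 in 26-35 mm tubers. With the replicate block these counts were 2365, 2498, 2962, 2649 and 2943. Of the lists compiled after the values were seen, starch metabolism had 4 of 7 tested genes higher and 0 lower, and 6 higher with the replicate block (camera adjusted p = 0.00133, and adjusted p = 0.219 with an estimated correlation). UDP-glucose pyrophosphorylase was 1.71 ± 0.45 higher as a gene mean. For the sucrose synthase SS16, 1 spot was 7.56 ± 0.42 higher while its other tested spots differed by -0.25 and -0.18 without passing, so its mean is not given. Of the fixed lists, 1 of 6 patatin spots could be tested, and it was higher, also when adjusted over the list alone. The auxin, cytoskeleton and heat shock lists had 0 spots past the threshold, also 0 when adjusted over the list alone, while with the replicate block 1 IAA3 spot was higher and 2 IAA2 spots lower. The sn1 spot tested did not pass, and it was lower when adjusted over the list alone and with the replicate block. The test of any difference among the 6 classes called 402 spots and 1589 with the replicate block. Without both stolon arrays it called 0 spots, and 779 without them and with the block.

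The comparison of large with small tubers asked what changes as tubers grow. No spot passed the threshold in the planned limma fit, with 0 of 10415 called and 757 at an unadjusted p under 0.05. The size change still repeated between the replicates, at r = 0.725 over 8011 spots, so 0 calls do not show that nothing changed. With the replicate as a block, 116 spots were higher and 20 lower in tubers of 16-35 mm than in those of 1-10 mm. With the block and without the stolon arrays, a fit added after the data were examined, 959 were higher and 1116 lower. The balance of the directions therefore depends on the stolon arrays, whose replicate deviations ran against those of the tubers (r of -0.47 to -0.37). A block shared with the stolons describes the tuber arrays less well. For 26-35 mm against 1-5 mm the planned fit also called 0 spots, with 699 at an unadjusted p under 0.05, and the blocked fit 117 higher and 16 lower. The named genes with the smallest p are therefore given as values not past the threshold in the planned fit. API differed by 4.23 ± 0.94 (adjusted p = 0.229, and 0.0241 with the block), KTI-C by 2.89 ± 0.73 (0.304 and 0.0129), CYP74D2 by 2.34 ± 0.38 (0.138 and 0.0313) and PIN-II by 1.56 ± 0.37 (0.265 and 0.0623). VPE2 differed by -3.89 ± 0.93 (adjusted p = 0.281, and 0.0296 with the block), StSSR1 by -1.03 ± 0.20 (0.167 and 0.0382) and the cyclophilin-like symbol cyp by -1.23 ± 0.32 (0.321 and 0.0623). ARD, the invertase PAIN-1 and pyrB passed neither in the planned fit nor with the block shared with the stolons. All blocked values of single genes given here are from that shared block. Values of single genes with the block and no stolon arrays are not given. Patatin differed by 1.41 ± 0.38 (adjusted p = 0.385), and its 1 spot passed when adjusted over the list alone. The other fixed lists with tested spots had 0 spots past the threshold, also 0 when adjusted over the list alone. Of the pathogenesis and sucrose lists 0 spots could be tested. The list of storage proteins and protease inhibitors, compiled after the values were seen, was higher in large tubers (camera adjusted p = 5.66e-05, and adjusted p = 0.243 with an estimated correlation). Of its 4 tested genes 0 passed over all genes, 4 when adjusted over the list alone and 2 with the replicate block. On gene means, 0 of 367 genes passed in the planned fit, and 7 were higher and 2 lower with the block.

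The last comparison asked whether ageing in culture and growth on the plant changed the same transcripts. The in vitro times began 2 days after induction, whereas the in vivo classes compared were all formed tubers. Stage and system therefore cannot be told apart in it. The difference between late against early microtubers and large against small tubers was itself tested over all 22 arrays, with 1 spread shared by both systems. Fitted apart, the prior standard deviation was 0.16 in vitro and 0.439 in vivo, so p-values of the shared fit may be too small. Of 11181 spots 454 differed, 218 with a higher and 236 with a lower change in vitro. This count depends on the unsettled in vivo direction and was 1121 with the other choice, and it was 1741 with the replicate block, 3674 with quantile normalization, 51 with array weights and 140 to 756 without single arrays. VPE2 changed by 1.31 ± 0.09 in vitro and by -3.89 ± 0.93 in vivo (difference 5.20 ± 1.02, adjusted p = 0.0161). PIN-II fell in vitro (adjusted p = 4.92e-04) and changed by 1.56 ± 0.37 in vivo (difference -3.56 ± 0.53, adjusted p = 0.00447). METK1, PAIN-1 and SpdSy, the spermidine synthase, differed by 2.26 ± 0.53, 1.16 ± 0.24 and 0.86 ± 0.16. PEST2, EI1, CS-B and CYP74D2 differed by -2.57 ± 0.51, -2.25 ± 0.25, -1.77 ± 0.40 and -1.62 ± 0.41. As means over all spots METK1 (2.31 ± 0.76, adjusted p = 0.0907, and 0.00214 with the block) and CYP74D2 (-1.43 ± 0.70, adjusted p = 0.249, and 0.0974 with the block) did not pass, and CS-B differed by -1.17 ± 0.25. TOM20 differed by 0.56 ± 0.17, not past the threshold (adjusted p = 0.0789, and 0.0322 with the block). With the other in vivo direction 3 of these 9 named differences passed the threshold, SpdSy with 0.71 (adjusted p = 0.014), EI1 with -1.10 (adjusted p = 0.0142) and CYP74D2 with 3.07 (adjusted p = 4.96e-04), the last with its sign turned. VPE2 was then -2.57 (adjusted p = 0.141) and PIN-II -0.43 (adjusted p = 0.708). Each of the in vivo changes of named genes was itself past no threshold in the planned fit. Across 9965 spots the changes of the systems had Pearson r = 0.169 and Spearman rho = 0.032, and 50.4% of spots had the same sign, where spots are not independent replicates. With the other direction r was -0.169, and without single in vivo arrays it ranged from -0.115 to 0.434. Fits without single arrays had no replicate block, so the loss of 1 tuber array mixes the replicate difference into the size contrast. With all arrays and the block Pearson r was 0.167, and it was 0.227 in replicate 1 and 0.145 in replicate 2 alone. Spearman rho was 0.0195 with the block, 0.126 in replicate 1 and -0.0868 in replicate 2, so its sign differed between the replicates. The share of spots with the same sign was 49.6%, 53.2% and 45.0% in that order. With the replicate block, 72 spots were higher in both where independent lists would share 24.9, and 13 were lower in both against 5.2. With the other direction these 72 and 13 spots changed oppositely in the systems, and 2 were higher in both against 4.7 and 4 lower in both against 27.5. Late against early changes were also set against tuber over stolon changes in the likely direction, with Pearson r = 0.141. It was 0.398 in replicate 1 and -0.0855 in replicate 2. In the planned fits 471 spots were higher in both where independent lists would share 376.6, and 217 lower in both against 243.7.

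**Figure D3:**
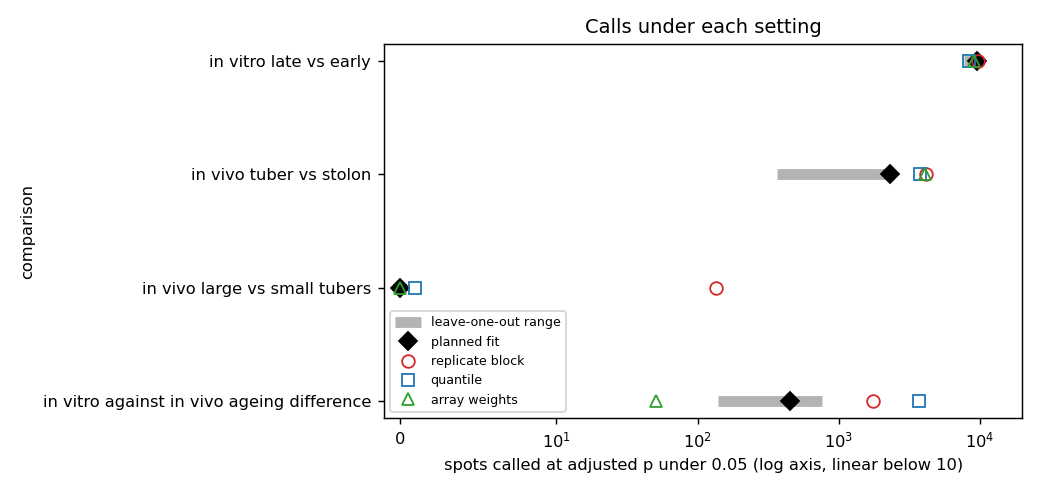
Number of spots called (horizontal axis, logarithmic above 10 and linear below) in 4 comparisons (vertical axis) in the planned fit and under other settings, with a bar for the range when each array is left out. The in vitro count lay between 7650 and 9685 in the settings drawn, whereas large against small tubers had 0 calls in the planned fit and 136 with the replicate block. The 2075 calls with the block and no stolon arrays are not drawn.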

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

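The tests of the replicate difference, of the dye bias, of the amplification and of other sample splits were chosen or written down only after the results were seen, and the test of the mean ratio was written down before. Ageing in vitro and growth in vivo differed at 454 spots by the test of the difference itself, which shared 1 spread over both systems. The named differences were 5.20 for VPE2, 2.26 for METK1, 1.16 for PAIN-1, 0.86 for SpdSy, -3.56 for PIN-II, -2.57 for PEST2, -2.25 for EI1, -1.77 for CS-B and -1.62 for CYP74D2, on the log2 scale. With the other in vivo direction they were -2.57, 0.71, -0.10, 0.71, -0.43, -0.78, -1.10, -1.17 and 3.07 in the same order, and only SpdSy, EI1 and CYP74D2 passed the threshold.

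For the difference between systems, the in vivo direction stays open. If the in vivo ratios ran the other way, the mean ratio over the 6 stages should lie closer to 1 with the sign turned. It lay farther from 1 for 50.8% (SE 0.74) of spots in replicate 1 and 51.9% (SE 0.68) in replicate 2, against 52.6% and 54.4% in vitro, which meets the wording fixed beforehand (over 50% in both) against the other direction, in replicate 1 by little more than its SE. The median distance from 1 went the other way, from 0.61 to 0.52 and from 0.34 to 0.27 on the log2 scale, while in vitro it moved little and both ways, from 0.073 to 0.070 and from 0.098 to 0.106. The demands on the median and for 2 standard errors were added after the result was seen, and in vitro replicate 1 also fails the one on the median, so the median is no sure sign of a wrong direction. The tails of the values go with the shares but served to choose the direction, so it is left open here, and the count of 454 may be 1121. In the splits, fitted as groups of arrays, 3 of 100 gave as many calls as the real split with 1058, and the highest other gave 4416. That highest split parted the in vivo arrays and the in vitro arrays by replicate, which points to a structure of the samples, and the blocked value of the comparison was 1741.

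For large against small tubers, the 0 calls of the planned fit go with a large difference between the in vivo replicates. Splitting the 8 tuber arrays by replicate called 5968 spots, against 0 for the split by size. The size change itself repeated between the replicates at r = 0.725. With 0 calls for the size split, the 35 of 35 splits with as many calls follow by construction and decide nothing. A dye bias that is the same on all arrays is argued against, since replicate deviations of stolons and tubers correlated at -0.37 or lower. It cannot exclude a dye bias shared by the tuber arrays alone, since only stolon RNA was amplified. Deviations of the tuber classes correlated at 0.85 to 0.93, which such a bias would also give. What part the dye and the set of plants each play cannot be told apart, as both follow the replicate number. With the replicate as a block in the 8-array fit, the size split called 1904 spots and the highest of the other balanced splits 0, with 1 of 18 splits as large, too few for a share under 0.05.

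For tubers against stolons, the amplification of the stolon RNA cannot be told apart from the tissue, because both stolon samples and no tuber sample were amplified. The change repeated between replicates at r = 0.507, which either would give. The tissue difference that the design names stays open and untested. For late against early microtubers, 1 of 35 splits, the real one with 8022 calls, gave as many, and the highest other gave 0, so a chance split of the arrays is argued against there.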

How the results depend on the processing

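The added settings, chosen after the data were examined, are the clone averages and the block without stolons. The in vitro counts stayed within 1.5 times in all settings but 2. With a 2-fold minimum they were 3264 (any difference), 2004 (late against early) and 2747 (30 against 2 days), and with clone averages, which test fewer features, 4078, 5276 and 4477. The in vitro replicates share only a number (4 of 10 pairs over 0.1), and the block gave 9685 calls for late against early.

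The in vivo counts depended on the setting. Any difference was called at 1589 spots with the replicate block, 1412 with quantile normalization, 1300 with array weights, 0 without the stolon arrays, 779 without them and with the block, and 0 to 230 without single arrays. Tuber against stolon gave 4126 with the replicate block, 3788 with quantile normalization, 4070 with array weights, 1388 with clone averages and 366 to 2152 without single arrays, and all 2324 calls change direction with the other in vivo sign. Large against small tubers gave 136 with the replicate block, 1 with quantile normalization and 2075 with the block and no stolons, and 26-35 against 1-5 mm gave 133, 1 and 1780. All other settings gave 0. The cause was not tested for quantile normalization and array weights.

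The difference between systems gave 1741 with the replicate block, 3674 with quantile normalization, 302 with values on every array, 688 with the looser filter, 51 with array weights, 297 with clone averages, 1121 with the other in vivo sign and 140 to 756 without single arrays. The cause was not tested. The Pearson correlation between systems was 0.287 for 30 against 2 days with 26-35 against 1-5 mm, and -0.169 with the other sign. It was 0.227 in replicate 1 and 0.145 in replicate 2, where Spearman rho was 0.126 and -0.0868. Without single arrays the Pearson correlation ranged from -0.115 to 0.434. It turned sign without the 16-25 or 26-35 mm array of replicate 1 or the 1-5 or 6-10 mm array of replicate 2. Fits without single arrays had no replicate block, so the loss of 1 tuber array mixes the replicate difference into the size contrast.

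The heat shock list lost its call with an estimated correlation (adjusted p = 0.359), and with 1 spot per gene no fixed list could be tested. Among added lists far from the threshold, the sign turned with 1 spot per gene in large against small tubers for kinases, polyamines, eIF5A and hormone genes (adjusted p = 0.956), in vitro for hormone genes and photosynthesis (0.992), with quantile normalization for photosynthesis and starch (0.976), and with the replicate block for starch (0.955). With the other in vivo sign the named tuber against stolon changes become -8.09 (KTI-C), -5.58 (API), -3.71 (ADH1), -3.63 (CYP74D2), -3.26 (GA2OX1), -3.24 (BEL5), -3.11 (PIN-II), -2.89 (dpeP), -2.62 (glgP), -2.30 (GBSS-II), 5.54 (FLS), 3.54 (XIP1-1-BETA), 3.07 (CAT1), 2.88 (PSBR), 2.87 (eIF-4D), 2.49 (METK1), 2.16 (MSP-II), 1.72 (p23), 1.53 (16R) and 1.49 (gln). Large against small become -2.34 (CYP74D2), -4.23 (API), -1.56 (PIN-II), -2.89 (KTI-C), -0.57 (ARD), 1.03 (StSSR1), 3.89 (VPE2), 1.23 (cyp), 0.63 (PAIN-1) and 0.59 (pyrB). The differences between systems change sign for VPE2 (-2.57), PAIN-1 (-0.10), TOM20 (-0.20) and CYP74D2 (3.07), and the in vivo list tests turn direction. No named gene changed sign in another setting. The named in vitro genes kept their call in all 200 fits without single arrays and all 171 under other settings. Named tuber against stolon genes lost it in 46 fits without single arrays and 11 under other settings, most often CAT1, gln and 16R. Named differences between systems lost it in 43 fits without single arrays and 11 under other settings. Leaving out an array assumes that its lone partner varies like the other groups. Signal over background was not used here.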

Other observations

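The tests in this part were made after the values were seen. Of the transcripts of eIF5A, a translation factor, the member listed as eIF-5A-5 rose in ageing microtubers by 1.06 ± 0.11 on the log2 scale and eIF-5A-1/2 changed by 0.02 ± 0.09. Among the 4 eIF5A genes tested there, 1 rose and 1 fell past the threshold (camera adjusted p = 0.792). In tubers against stolons all 4 tested eIF5A genes had a lower mean in the likely direction, of which 1 passed the threshold (eIF-5A-1/2, -2.76 ± 0.50) and 3 with the replicate block. Of the S-adenosylmethionine genes, METK1 rose in microtubers by 1.54 ± 0.12 and METK2 changed by -0.42 ± 0.09. Among oxylipin genes, POTLX-3 rose in microtubers while the hydroperoxide lyase HPL changed by -0.76 ± 0.15. The mean of the divinyl ether synthase CYP74D2 went from -1.59 at 2 days to 0.61 at 5 days and 0.12 at 30 days, so its higher level at the late times comes from the 2 day arrays.

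Patatin had 0 of 60 possible values on the in vitro arrays and 35 of 72 on the in vivo arrays, and KTI-C had 4 of 140 and 95 of 168. As the spot filtering is not given, missing values do not show that a transcript was absent. The reference pools closed differently. The log2 mean ratio over the stages had an SD of 0.125 and 0.172 in the in vitro replicates and of 0.885 and 0.547 in the in vivo replicates.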
